A study of Homo sapiens with 6 samples.

How the data were processed

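RNA sequencing libraries from cardiomyocytes made from induced pluripotent stem cells of the IMR90 line, a human lung fibroblast line, were compared between 3 control and 3 ethanol-treated samples. The labels place all 6 samples at day 30 or later of culture. They give neither the ethanol dose nor the length of exposure. Groups and replicate numbers were taken from the sample titles. Control columns of the deposited table were matched to the titles by group name and number, and ethanol columns by their initial E, their replicate number and elimination. The ethanol columns also carry a number that the labels do not explain.

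The deposited values were raw read counts per Ensembl gene, with no normalization, as their whole numbers and differing library totals show. HISAT2, HTSeq, DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without versions or roles. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. All 58735 gene identifiers in the table were found in GENCODE release 29, which supplied symbols, coordinates on GRCh38, exon lengths and GC content. No row lacked a gene, and 27938 genes had no count in any library. Because the strand setting is unknown, reads from overlapping genes on opposite strands cannot be assigned with certainty. The share of exon bases that overlap another gene was therefore computed for genes named by the rule below, except CAT. It was not computed for genes chosen after their values were seen. Symbols are those of release 29, so CTGF and CYR61 stand for CCN2 and CCN1.

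Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with enough counts by edgeR's filterByExpr were kept, which left 16555, and library sizes were scaled by TMM factors. Ethanol was compared with control by edgeR's quasi-likelihood test (two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are CPM with TMM scaling, given as mean ± SD over 3 libraries. Standard errors of log2 fold changes were derived from the fold change and the F statistic of the test. Fold changes are ethanol over control.

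Before the data were examined, 34 gene lists, the rule for named genes and the alternatives were fixed. Named genes were the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out clone-based names. Up to 4 members with the smallest p among those past the threshold were named for each list, or the most abundant member where none passed. ADH5, ALDH2, CYP2E1, CAT, MYH6, MYH7, NPPA, NPPB, TNNT2 and GDF15 were named whatever their result. Some genes that this rule selected are not reported here. Other genes named in the text were chosen after their values were seen. Lists with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera with a correlation estimated per list, and fry, which tests a list without reference to other genes, were run beside it. Member counts are also given adjusted over the list alone.

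The alternatives were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, DESeq2 1.42.0 and limma-voom in place of the quasi-likelihood test, and robust dispersion estimation. No filter on low counts, a filter of 1 CPM in 3 libraries, and a count table without mitochondrial genes were also tried. The replicate number was added as a block, each library was left out in turn, and stricter thresholds were applied (adjusted p under 0.01, and a test against a fold change of 1.2). After the data were seen, fits were added in which a trend on GC content (natural spline, 5 degrees of freedom), or on GC content and gene length, was removed from each library through the offsets. 3 gene lists were also added then, and their p-values were adjusted over these 3 lists alone. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

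The test was checked on simulated counts with the real means and library sizes, in which 200 genes with a mean of at least 5 CPM were changed. Recovery was not measured for weaker genes. edgeR recovered 44% of genes changed 1.3-fold, 80% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, and it called 8 of 16355 unchanged genes. When GC trends were added to the simulated libraries, 75 unchanged genes were called without GC correction and 7 with it. Recovery without GC correction was then 34% at 1.3-fold and 76% at 1.5-fold, and with it 46% and 86%. No library was left out. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which can be technical.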

Results

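Gene expression was measured by RNA sequencing in cardiomyocytes differentiated from IMR90 induced pluripotent stem cells, in 3 control and 3 ethanol-treated libraries. The comparison asks which transcripts differ after exposure to ethanol, which the series title calls long-term. Total counts were 18753247, 17560864 and 18579208 in control replicates 1 to 3, and 17331532, 19266076 and 17727912 in ethanol replicates 1 to 3. Group means of the totals differed by less than the spread between libraries (exact permutation test, two-sided p = 0.9, where 0.1 is the smallest p that 3 against 3 can give). Of the genes in the table, 16555 had enough counts to be tested.

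In the ethanol-treated cardiomyocyte cultures, 13 of 18 tested hypoxia-inducible transcripts were higher and 1 lower, and 11 of 20 glycolytic transcripts were higher. Lower were 19 of 26 matrix and 9 of 17 immediate early transcripts. Camera called these 4 lists with a preset correlation, and the calls were lost when it was estimated (in the same order, adjusted p = 0.106, 0.305, 0.207 and 0.0997 with an estimated correlation). Fry, which makes no comparison with other genes, called all 4 (in the same order, adjusted p = 0.00830, 0.0375, 0.0357 and 0.00522). In all, 1649 of the 16555 tested genes passed the threshold, 727 higher and 922 lower, and 119 of those past it changed by more than 2-fold. The number of calls in a list, here and below, has to be read against that share over all genes. Changes were ranked among genes past the threshold with at least 5 CPM in the higher group, no overlap between groups and no clone-based name. The largest rise among these genes was that of BHLHE40 (ENSG00000134107, chromosome 3, 4979116 to 4985323), a transcriptional repressor of the circadian and hypoxia responses. It went from 109 ± 7.27 to 292 ± 11 CPM (SD, n = 3 each), with a log2 fold change of 1.42 (SE 0.08, adjusted p = 2.77e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ADM (ENSG00000148926, chromosome 11, 10304680 to 10307397), which encodes the vasodilator peptide adrenomedullin, rose from 25.1 ± 0.858 to 66.1 ± 7.78 CPM. HILPDA, which coats lipid droplets, rose from 29.6 ± 2.62 to 66.7 ± 1.75 CPM, and STC1, a secreted glycoprotein, from 18.4 ± 2.35 to 41.5 ± 2.59 CPM. DDIT4, an inhibitor of mTORC1 signalling, rose 2.24-fold, although 41.2% of its exon bases overlap an antisense gene. NRN1 and FGF23, a phosphate-regulating hormone, rose by 1.21 and 1.23 on the log2 scale. FGF23 was weakly expressed, at 2.36 ± 0.184 CPM in controls and 5.56 ± 1.84 CPM in ethanol. LDHAP4, which rose from 3.88 ± 0.711 to 9.63 ± 3.06 CPM, is a processed pseudogene of LDHA, and reads of the 2 can be exchanged.

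The most abundant of the 8 genes with the largest falls was ELN (ENSG00000049540, chromosome 7, 74027789 to 74069907), which encodes elastin and went from 1461 ± 187 to 653 ± 127 CPM (log2 fold change -1.16, SE 0.12, adjusted p = 1.11e-05). Weakly expressed genes fell further, namely COL9A2 (-1.46 on the log2 scale), the myosin MYO7B (-1.45) and the adhesion molecule CEACAM5 (-1.44), at means of 5.16, 6.94 and 5.75 CPM in controls. FOSB, a subunit of the AP-1 transcription factor, fell from 32.3 ± 4.18 to 14.6 ± 3.57 CPM. SLC26A7, an anion transporter, and TTR, a carrier of thyroid hormone, had log2 fold changes of -1.12 and -1.11 at 6.02 and 6.10 CPM in controls. ILK, with a log2 fold change of -1.22, overlaps genes on the opposite strand over 78.5% of its exon bases and is uncertain. The call of TTR ended without control replicate 1 or 2. The number of genes past the threshold was 504 without control replicate 2, 649 without control replicate 1, 1024 without ethanol replicate 3 and 3308 without ethanol replicate 1, and those over 2-fold numbered 47, 57, 65 and 195 in these fits. The number of higher genes was 475 without control replicate 3 and 466 without ethanol replicate 2.

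Of 18 tested members of the hypoxia response list, 13 were higher and 1 lower, with a median log2 fold change of 0.45, and adjusted over the list alone the counts were 14 and 1. Camera placed the list above other genes (adjusted p = 2.29e-19), and the call was lost with an estimated correlation (adjusted p = 0.106 with an estimated correlation). After ADM and DDIT4, the members with the smallest p were BNIP3, a mitophagy receptor, which rose from 608 ± 49.6 to 974 ± 71.8 CPM, and the prolyl hydroxylase EGLN3, which rose from 94.9 ± 9.43 to 135 ± 5.08 CPM. LOX and VEGFA were chosen after their values were seen. LOX, a collagen cross-linking enzyme that is also on the matrix list, was the member that fell (log2 fold change -0.29, adjusted p = 0.0479), and 0 members were lower in the 5 fits that left out a library other than ethanol replicate 3. VEGFA, the endothelial growth factor, did not pass the test (0.22, SE 0.11), but passed it with a GC trend removed per library (0.33, adjusted p = 0.0167).

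In the glycolysis list 11 of 20 tested members were higher and 0 lower, with a median log2 fold change of 0.32, and 13 higher and 1 lower when adjusted over the list alone. The camera adjusted p was 5.85e-11, and the adjusted p = 0.305 with an estimated correlation. Without control replicate 2, 6 members were higher, and 1 was lower without ethanol replicate 1. GAPDH rose from 4000 ± 152 to 6301 ± 669 CPM and PGK1 from 1523 ± 126 to 2344 ± 158 CPM. LDHA, which makes lactate, rose 1.45-fold, and the glucose transporter SLC2A1 rose 1.42-fold from 422 ± 20.5 CPM. Pseudogenes of GAPDH, PGK1 and LDHA exist, so reads can be divided between copies.

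**Figure D1:**
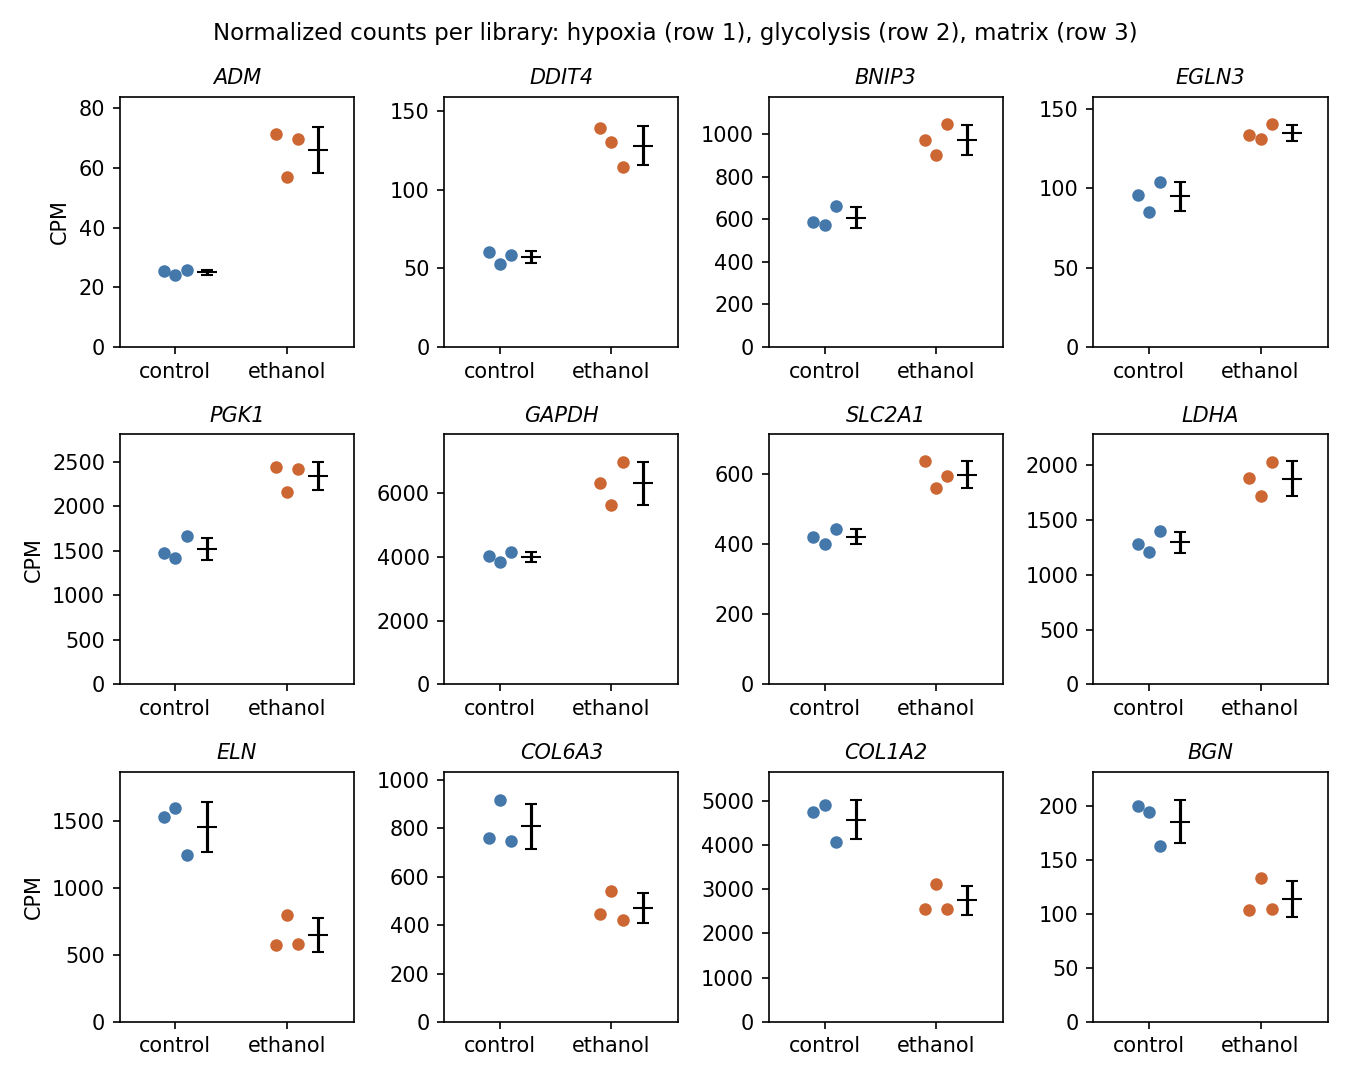
Normalized counts (CPM, linear axis from 0) in each library for 4 hypoxia, 4 glycolysis and 4 matrix genes, with points for the 3 control and 3 ethanol libraries and bars for the mean ± SD. Among them, ADM lay at 25.1 against 66.1 CPM and ELN at 1461 against 653 CPM.

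Of 26 tested members of the matrix and fibrosis list, 19 were lower and 0 higher, with a median log2 fold change of -0.49, and adjusted over the list alone 22 were lower and 1 higher. The camera adjusted p was 2.1e-23, and the adjusted p = 0.207 with an estimated correlation. Besides ELN, the type VI collagen gene COL6A3 fell from 808 ± 93.3 to 471 ± 63.4 CPM, the type I collagen gene COL1A2 from 4573 ± 445 to 2748 ± 330 CPM, and the proteoglycan gene BGN from 185 ± 19.8 to 114 ± 16.7 CPM. TGFB2, a growth factor chosen after its values were seen, was the member higher over the list alone and did not pass over all genes (0.21, SE 0.09). A fit without ethanol replicate 1 called 1 matrix member higher.

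Of 12 fibroblast markers, 6 of which are also on the matrix list, 7 were lower and 0 higher, and adjusted over the list alone 9 were lower and 0 higher (camera adjusted p = 5.85e-11, adjusted p = 0.297 with an estimated correlation). COL1A1 and COL3A1 had log2 fold changes of -0.69 and -0.63, and the growth factor receptor PDGFRB fell from 283 ± 26.4 to 174 ± 19.5 CPM. In controls COL1A1 and COL3A1 had means of 6921 and 11734 CPM, and the cardiac myosin gene MYH6 had 13333 CPM. The libraries are bulk, so changes cannot be assigned to a cell type. Smooth muscle markers went both ways, with 3 of 9 lower and 1 higher, and the same counts adjusted over the list alone. TAGLN, SMTN and ACTA2 had log2 fold changes of -0.79, -0.47 and -0.31, and MYOCD, a coactivator of serum response factor, rose by 0.36. Without control replicate 2, 1 smooth muscle marker was lower, and the number higher was 0 without control replicate 1 and 2 without ethanol replicate 1. ACTA2 shares 30.1% of its exon bases with genes on the other strand. Of 12 epicardial markers, the keratins KRT8 and KRT18 and LRRN4 were lower and KRT19 was higher, with 4 lower and 1 higher adjusted over the list alone. The calls of KRT8, KRT18 and LRRN4 ended when a GC trend was removed per library, and also without control replicate 1 or 2, where 0 epicardial markers were lower. The call of KRT19 ended without control replicate 2 or 3. The epicardial list passed camera without ethanol replicate 2 (adjusted p = 0.0170), and the endoderm list without control replicate 3 (adjusted p = 0.0186). ERG was the 1 lower gene of 6 endothelial markers (2 lower adjusted over the list alone), and TTR the 1 lower gene of 16 endoderm markers (2 lower adjusted over the list alone). Both calls ended without control replicate 1 or 2, and 2 endothelial markers were lower without ethanol replicate 3. STMN2 was the 1 higher gene of 6 neural markers and ACTN3 the 1 higher gene of 4 skeletal muscle markers, with the same counts adjusted over the list alone, and the call of STMN2 held in 1 of the 6 fits that left out a library. None of 4 pluripotency markers passed with edgeR in either adjustment, DNMT3B being the most abundant (-0.32, SE 0.14), and 2 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0. In edgeR's fit of all 6 libraries with TMM factors, camera called none of the lists from smooth muscle to pluripotency markers, but the smooth muscle list passed with DESeq2 (adjusted p = 0.0427) and the epicardial list with DESeq2 (adjusted p = 0.00816) and with no filter on low counts (adjusted p = 0.0249).

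**Figure D2:**
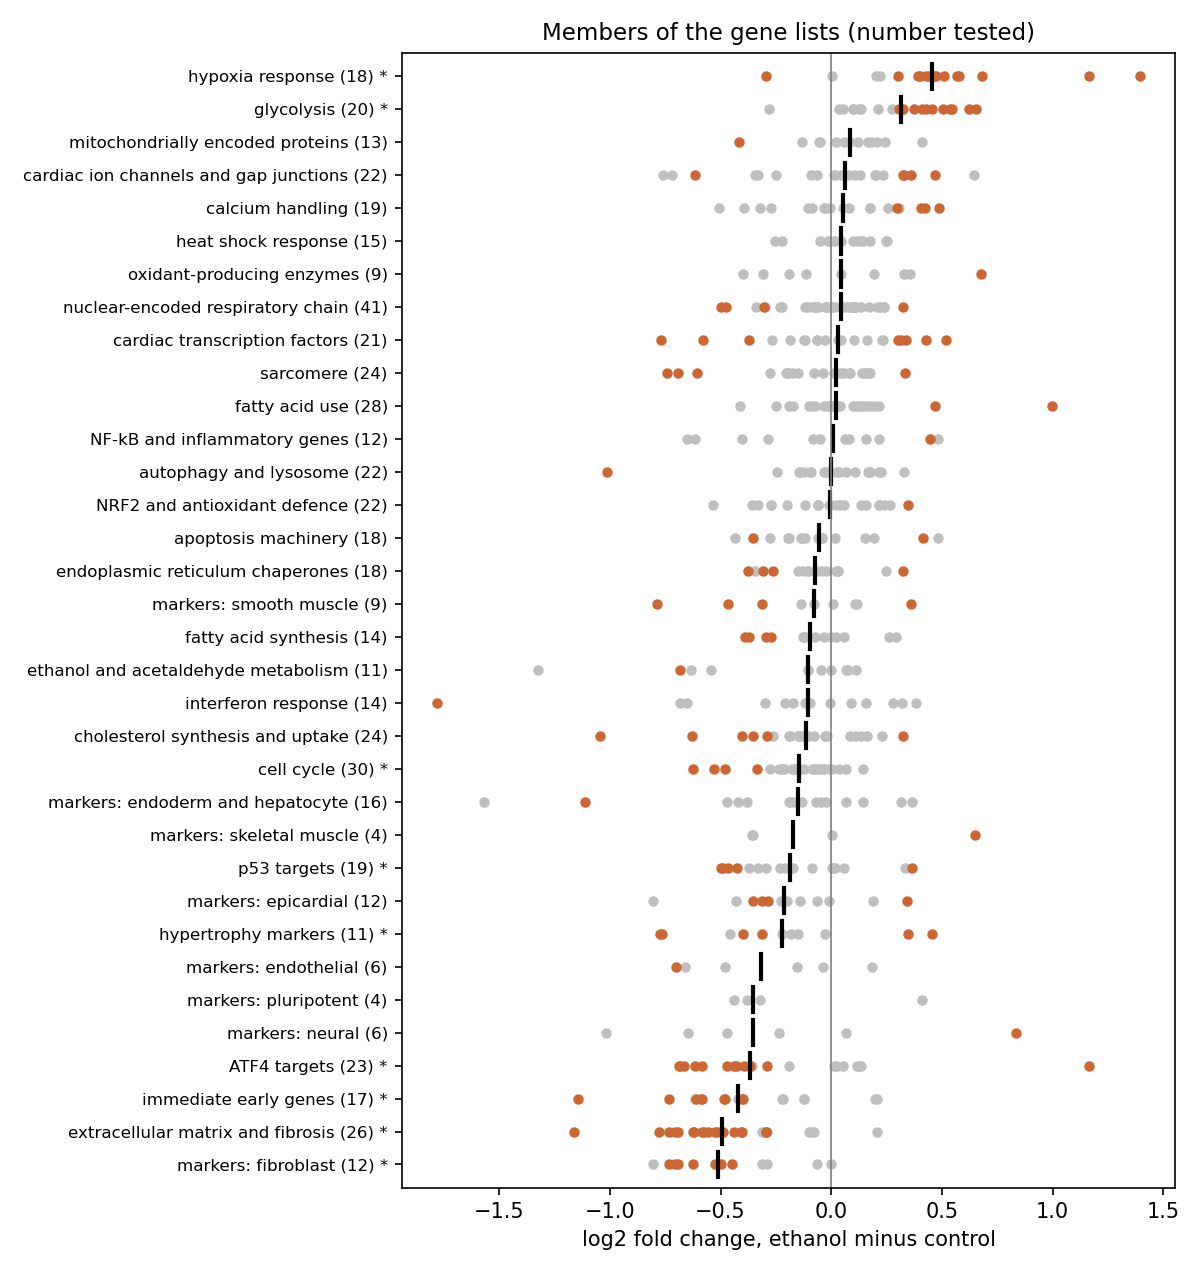
Log2 fold changes (ethanol minus control) of the tested members of the 34 gene lists, ordered by median, with orange points for genes past the threshold, grey points for the others, a black bar for the median and an asterisk for the 9 lists past the camera threshold. Medians run from -0.51 for fibroblast markers to 0.45 for the hypoxia response.

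Immediate early genes, which respond within minutes to growth and stress signals, were lower in 9 of 17 tested members and higher in 0, with 10 lower when adjusted over the list alone. Their median log2 fold change was -0.42 (camera adjusted p = 4.05e-10, adjusted p = 0.0997 with an estimated correlation), and with GC correction 7 members were lower and the median was -0.26. EGR1 fell from 201 ± 10.6 to 121 ± 15 CPM, FOS from 156 ± 9.90 to 112 ± 4.31 CPM and the matricellular gene CYR61 from 133 ± 12.1 to 88.3 ± 6.89 CPM. Targets of ATF4, the transcription factor of the amino acid response, were lower in 12 of 23 and higher in 1, which was DDIT4, and adjusted over the list alone the counts were 13 and 1 (median -0.37, camera adjusted p = 5.38e-05, adjusted p = 0.281 with an estimated correlation). Without control replicate 1 or 2, 7 targets were lower. The amino acid transporter SLC7A5 fell from 162 ± 18.8 to 101 ± 10.3 CPM, and NUPR1 and CHAC1 had log2 fold changes of -0.69 and -0.67. GDF15, a stress hormone, did not pass (-0.42, SE 0.29).

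Hypertrophy markers were lower in 4 of 11 and higher in 2, with 6 lower and 2 higher adjusted over the list alone (camera adjusted p = 9.57e-04, adjusted p = 0.198 with an estimated correlation). ANKRD1, a titin-binding stress protein, fell from 250 ± 11.7 to 146 ± 16.4 CPM, and skeletal actin ACTA1 from 67.8 ± 4.15 to 40.0 ± 3.92 CPM. XIRP1 (-0.40) and TNC (-0.31), a matrix glycoprotein chosen after its values were seen, were lower, and FHL2 (0.35) and the natriuretic peptide gene NPPB (0.45, adjusted p = 0.0215) were higher, while NPPA did not pass (-0.15, SE 0.09), and 25.5% of its exon bases overlap CLCN6. Without control replicate 1 or 2, 0 hypertrophy markers were higher, and without control replicate 2, 2 were lower. The cell cycle list was lower in 4 of 30 members (5 adjusted over the list alone), namely the mitotic genes CDC20, PLK1, AURKB and MKI67, with log2 fold changes from -0.62 to -0.34 (camera adjusted p = 0.00292, adjusted p = 0.426 with an estimated correlation). The cell cycle list lost its call without ethanol replicate 1 (adjusted p = 0.0709), and 2 members were lower without control replicate 1, control replicate 2 or ethanol replicate 3. Of 19 p53 targets, AEN (-0.49), PHLDA3 (-0.43), BBC3 (-0.50) and TP53I3 (-0.47, chosen after its values were seen) were lower, and CCNG1 (0.36) was higher, with 6 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0263, adjusted p = 0.281 with an estimated correlation). The p53 list lost its call without control replicate 3 (adjusted p = 0.0583), and the number lower was 1 without control replicate 1, control replicate 2 or ethanol replicate 3, and 9 without ethanol replicate 1. The number of p53 targets higher was 0 without control replicate 1, control replicate 2 or ethanol replicate 3, and 2 without ethanol replicate 1. The call of BBC3 ended with GC correction.

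Of 24 sarcomere genes, 3 were lower and 1 higher, and the counts were the same adjusted over the list alone. Without ethanol replicate 1, 9 were lower and the list passed camera (adjusted p = 0.00432). In that fit, and without any 1 control replicate, 0 were higher. With GC correction, 2 to 4 were lower when 1 library was left out, and the list then did not pass. MYH7, the slow cardiac myosin heavy chain, fell from 1899 ± 99.3 to 1175 ± 167 CPM (log2 fold change -0.69, SE 0.10, adjusted p = 2.94e-04), and the ventricular light chain MYL2 fell from 29.3 ± 1.59 to 17.5 ± 1.34 CPM. Cardiac troponin TNNI3 was lower (-0.61) and the fetal form TNNI1 higher (0.33). MYH6 (0.14, SE 0.13) and TNNT2 (0.03, SE 0.13) did not pass, and MYH6 and MYH7 are close paralogs that can share reads. Calcium handling genes were higher in 4 of 19 and lower in 0, with 6 higher and 3 lower adjusted over the list alone. These were ASPH (0.49), the junctional protein TRDN (0.40), and the calcium channel subunits CACNA1D (0.42) and CACNB2 (0.30), and 2 were higher without control replicate 1 or 2. Leaving out ethanol replicate 1 or 3 gave 1 lower. Ion channel and gap junction genes were higher in 4 of 22 and lower in 1, with 5 and 2 adjusted over the list alone. The pump subunit ATP1B1, the potassium channel KCNJ3 and the connexin GJA5 rose by 0.36, 0.33 and 0.32, as did the channel subunit KCNIP2 (0.47, chosen after its values were seen), and the atrial potassium channel KCNA5 had a log2 fold change of -0.62. The number higher was 0 without control replicate 2, and 2 without control replicate 1 or ethanol replicate 2, and 2 were lower without control replicate 3 or ethanol replicate 3. Of 21 cardiac transcription factors 5 were higher and 3 lower (6 and 3 adjusted over the list alone), with TBX5 (0.52) and ESRRG (0.43) rising, and NR2F1 (-0.77) and NR2F2 (-0.58) falling. The others were MEF2C (0.34), TBX2 (0.32), MEF2A (0.30) and ESRRA (-0.37), chosen after their values were seen. The number higher was 1 without control replicate 1 or 2, 3 without ethanol replicate 2 and 2 without ethanol replicate 3, and 1 was lower without control replicate 2. Camera called none of these 4 lists in edgeR's fit of all 6 libraries with TMM factors, but the calcium list passed, as higher, with DESeq2 (adjusted p = 0.0333) and the transcription factor list with GC correction (adjusted p = 0.0289).

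Of 41 nuclear-encoded respiratory chain genes, COX8A (-0.50), NDUFS7 (-0.48) and ATP5MC1 (-0.31) were lower and COX7B (0.33) was higher, and the counts were the same adjusted over the list alone. COX8A and NDUFS7 share 34.5% and 49.1% of their exon bases with other genes, and the calls of NDUFS7 and COX7B ended with GC correction. Without ethanol replicate 1, 6 were lower, the number higher was 2 without ethanol replicate 1 or 2, and it was 0 without ethanol replicate 3 or any 1 control replicate. Of 13 mitochondrially encoded genes only MT-ATP8, which overlaps MT-ATP6, was lower in either adjustment (-0.41, SE 0.13). The number lower was 0 without ethanol replicate 2 or any 1 control replicate, and the number higher was 2 and 1 without ethanol replicates 1 and 2. Mitochondrially encoded genes took 7.30% of the counts in ethanol replicate 3 and from 5.11% to 5.57% in the other libraries, and their list passed camera, as lower, without ethanol replicate 3 (adjusted p = 0.0334), where its direction with all 6 libraries was higher (adjusted p = 0.602). In fatty acid use, ANGPTL4, an inhibitor of lipoprotein lipase, rose from 14.1 ± 1.84 to 28.2 ± 4.25 CPM, and the lipid droplet protein PLIN2 from 53.2 ± 0.519 to 73.5 ± 4.34 CPM. The other 26 members of that list did not pass in either adjustment, although 3 members were lower without ethanol replicate 1. Cholesterol genes were lower in 5 of 24 and higher in 1 in both adjustments, among them MVD (-0.40) and SC5D (0.32), with LSS (-0.29) and CYP51A1 (-0.63) chosen after their values were seen. The number lower was 2, 1 and 3 without control replicates 1, 2 and 3, and 2 without ethanol replicate 3, and in these 4 fits 0 were higher. The cholesterol list passed camera without control replicate 2 (adjusted p = 0.0368) or ethanol replicate 1 (adjusted p = 0.0288). Fatty acid synthesis genes were lower in 4 of 14, namely FASN (-0.39), FADS2 (-0.27), ACLY (-0.29) and DGAT1 (-0.37), with 4 lower and 2 higher adjusted over the list alone. The number lower was 1, 0 and 2 without control replicates 1, 2 and 3, and 2 without ethanol replicate 2 or 3, and 2 were higher without ethanol replicate 1. In edgeR's fit of all 6 libraries with TMM factors, the filter on low counts, no covariate and no GC correction, none of these 5 lists passed camera. The cholesterol list passed, as lower, with DESeq2 (adjusted p = 0.00396), no filter (0.0116), upper-quartile factors (0.0468), library totals (0.0488) and GC and length correction (0.0493). GC correction ended the calls of MVD, SC5D, FASN, FADS2 and DGAT1.

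No enzyme of ethanol oxidation that was tested rose past the threshold. Of 11 tested members of the ethanol and acetaldehyde list, ALDH1A1, a retinaldehyde and acetaldehyde dehydrogenase, was the only one past the threshold in either adjustment, and it fell from 21.3 ± 0.982 to 13.2 ± 3.21 CPM (log2 fold change -0.69, SE 0.14, adjusted p = 0.00454). ADH5 (0.08, SE 0.08), ALDH2 (-0.11, SE 0.09) and CYP2E1 (0.07, SE 0.24) did not pass. CAT had 1, 5 and 0 counts in controls and 1, 3 and 8 in ethanol, too few to test. Of 22 antioxidant genes PRDX1 was higher (0.35), and of 9 oxidant-producing enzymes DUOX2 was higher (0.67), each the only call in either adjustment. The call of PRDX1 ended without control replicate 2, and that of DUOX2 without control replicate 1 or 3 or ethanol replicate 2 or 3. Leaving out ethanol replicate 1 gave 4 antioxidant genes higher and 1 lower, and 1 oxidant-producing enzyme lower. Endoplasmic reticulum chaperones were lower in 3 of 18 and higher in 1, with 3 and 2 adjusted over the list alone, namely HYOU1, CRELD2, CALR and DNAJB9, and these 4 calls ended with GC correction. The number lower was 0 without control replicate 1, control replicate 2 or ethanol replicate 3, and 1 without ethanol replicate 2, and the number higher was 2 without ethanol replicate 1 and 0 without control replicate 2 or 3 or ethanol replicate 2 or 3. None of 15 heat shock genes passed with edgeR in either adjustment, the most abundant being HSPB1 (-0.05, SE 0.09, and 0.16 with GC correction). There 5 had an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0, and 1 was higher and 1 lower without ethanol replicate 1. Among apoptosis genes MCL1 was lower (-0.35) and CASP9 higher (0.41), the only calls of 18 in either adjustment, but 3 were lower without ethanol replicate 1 and 0 higher without control replicate 2. In the autophagy list GABARAP was the 1 lower gene of 22 (-1.01, SE 0.30), with 0 adjusted over the list alone, and 55.7% of its exon bases overlap other genes. Its call held in 1 of the 6 fits that left out a library, and without ethanol replicate 1 the list had 4 genes higher and 0 lower. VCAM1 was the 1 higher gene of 12 inflammatory genes (0.44), and IFI44, at 1.16 CPM in controls, the 1 lower gene of 14 interferon response genes (-1.78), in either adjustment. Leaving out ethanol replicate 1 gave 2 inflammatory genes higher and 2 lower and 1 interferon response gene higher, and the call of IFI44 ended without ethanol replicate 2 or any 1 control replicate. None of these lists passed camera with all 6 libraries. With GC correction and 1 library left out, the ethanol list passed, as lower, without control replicate 2 (adjusted p = 0.0492), and the chaperone list without control replicate 3 (0.0229) or ethanol replicate 2 (0.0417). Median, mean and camera direction differed in sign for the sarcomere, ion channel, respiratory chain, antioxidant, inflammatory, autophagy and skeletal muscle lists.

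Among the 3310 genes with the lowest GC content 273 were higher and 35 lower, and among the 3310 with the highest GC content 55 were higher and 460 lower. The correlation of each library's deviations with GC content was 0.431, 0.232 and 0.141 in controls, and 0.173, -0.332 and -0.517 in ethanol (exact permutation test of the group difference, two-sided p = 0.2). The first principal component, with 40.2% of the variance, separated the groups, and ethanol replicate 3 lay farthest from the controls on it. With a GC trend removed per library, 1738 genes passed, 979 higher and 759 lower, so that 56.3% of calls were higher against 44.1% without the correction, and 1152 genes were called in both fits. With that correction 14 hypoxia genes and 16 glycolytic genes were higher, and 18 matrix genes, 8 fibroblast markers, 7 immediate early genes, 11 ATF4 targets, 4 hypertrophy markers, 7 cell cycle genes and 2 p53 targets were lower. It also gave 8 cardiac transcription factors and 4 sarcomere genes higher, 2 ion channel genes and 2 endothelial markers lower, and 3 cholesterol genes and 1 fatty acid synthesis gene lower. Antioxidant and inflammatory genes each had 2 higher with that correction. Calls in a direction with 0 before it were 1 lower for calcium handling, antioxidant and heat shock genes, and 1 higher for heat shock, interferon and autophagy genes.

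Of the 101 genes past the threshold that the rule for named genes selected, 55 kept their call in each of the 6 fits that left out 1 library, and 54 of these also kept it with GC correction. These 54 include ADM, BNIP3, EGLN3, GAPDH, PGK1, LDHA, SLC2A1, ELN, COL6A3, COL1A2, BGN, EGR1, FOS, SLC7A5, ANKRD1, MYH7, MYL2 and ALDH1A1. Calls that held in at most 2 of those 6 fits include DUOX2, TNNI1, CACNB2, KCNJ3, ATP5MC1, MT-ATP8, GABARAP, STMN2, IFI44, MKI67, PHLDA3, COX7B, SC5D, FADS2, ACLY, DGAT1, DNAJB9, CRELD2, CALR and LRRN4. The calls of XIRP1, ATP1B1, NR2F2 and FASN ended without control replicate 2, that of MYOCD without control replicate 1, and those of FHL2, CACNA1D, ACTA2 and NPPB without control replicate 1 or 2. The calls of MVD, ESRRG, HYOU1, CCNG1, BBC3 and AURKB ended without control replicate 1, control replicate 2 or ethanol replicate 3. SMTN lost its call without control replicate 2 or 3, GJA5 without these or ethanol replicate 2, and TNNI3 without control replicate 1 or ethanol replicate 2. PRDX1, TNNI3, GJA5 and CYP2E1 share 24.9%, 24.4%, 20.3% and 23.9% of their exon bases with other genes and are uncertain. Smaller shares were found in other named genes, such as PHLDA3 (19.1%), KRT18 (16.3%), CEACAM5 (16.2%), GAPDH (14.2%), HILPDA (13.2%), CACNB2 (13.0%), PLK1 (12.5%) and TAGLN (11.4%). Calls lost numbered 35, 43 and 19 without control replicates 1, 2 and 3, and 3, 16 and 22 without ethanol replicates 1, 2 and 3. At an adjusted p under 0.01, 38 of the 101 lost the call. In the test against a fold change of 1.2, 60 lost it, among them ALDH1A1 (adjusted p = 0.0538).

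**Figure D3:**
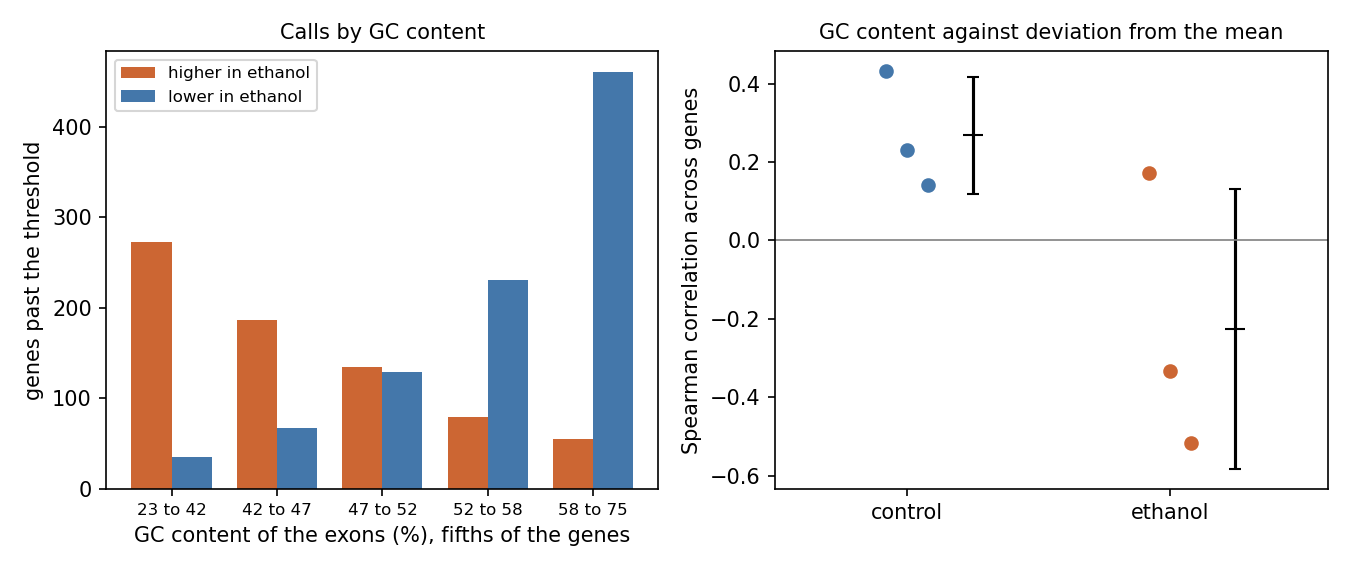
Left, genes past the threshold (number) in 5 equal bins of the tested genes by exonic GC content (%), higher in ethanol in orange and lower in blue. Right, Spearman correlation across genes between GC content and each library's deviation from the mean, with points for libraries and bars for the mean ± SD of 3, where ethanol libraries run from -0.517 to 0.173 and controls from 0.141 to 0.431.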

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

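The fits with GC correction were chosen after the data were seen, and the other alternatives before. The count of 1649 genes stayed within 1.5 times under the other normalizations, DESeq2, limma-voom, robust estimation, both filters, removal of mitochondrial genes and GC correction. It was 575 at an adjusted p under 0.01 (236 higher, 339 lower, 39 over 2-fold) and 250 against a fold change of 1.2 (96 higher, 154 lower, 41 over 2-fold), as those thresholds are stricter. DESeq2 gave 62 genes over 2-fold, and GC and length correction 1094 higher genes. The cause was not tested for these. The replicate block gave 2619 genes (1264 higher), but with GC correction it gave 1570 genes against 1738 without the block. Same-numbered libraries deviated with correlations of -0.018, 0.042 and -0.0050. Pairing by number was thus not seen, although such correlations across all genes cannot exclude it. Not every library correlated best with its own number, as control replicate 1 did so with ethanol replicate 3 (0.0516). Leaving out 1 library, with or without GC correction, gave 504 to 3308 genes, 201 to 1560 higher, 303 to 1748 lower, 47 to 195 over 2-fold and 9 to 14 lists. The lowest counts of genes came without control replicate 2 and the highest without ethanol replicate 1. With GC correction the range was 718 to 1793 genes, and the fit without ethanol replicate 1 gave 1793 against 3308. Of the 101 genes past the threshold that the rule for named genes selected, those that lost the call numbered 35, 43 and 19 without control replicates 1, 2 and 3, and 3, 16 and 22 without ethanol replicates 1, 2 and 3. At totals from 17331532 to 19266076, simulated changes of 1.3-fold were found in 44% of genes with a mean of at least 5 CPM. With GC trends added to the simulated libraries and no GC correction, the share was 34%. Small changes can thus be missed, and recovery for weaker genes was not measured.

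With a correlation estimated per list, 0 of the 9 lists passed (adjusted p 0.207 for matrix, 0.106 hypoxia, 0.305 glycolysis, 0.297 fibroblast, 0.0997 immediate early, 0.281 ATF4, 0.198 hypertrophy, 0.426 cell cycle and 0.281 p53). The p53 list (0.0263) missed a threshold of 0.01. With fry, which makes no comparison with other genes, only cell cycle of the 9 lists was lost (0.0548). Ethanol metabolism (0.0444), endothelial (0.00830) and smooth muscle (0.0390) lists were gained with fry, all lower. Calls gained with DESeq2 were calcium handling (0.0333, higher), cholesterol (0.00396), epicardial (0.00816) and smooth muscle (0.0427). The cholesterol list also passed with library totals (0.0488), upper-quartile factors (0.0468), no filter (0.0116), the replicate block (0.0438) and GC and length correction (0.0493). The epicardial list passed with no filter (0.0249). Cardiac transcription factors passed with GC correction (0.0289), with GC and length correction (0.0259) and with GC correction and the block (0.0219). The cause was not tested for these list calls.

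Some directions turned without a call in the fits named next. The respiratory chain list turned lower with no filter (0.930), the block (0.993), GC correction (0.961), GC and length correction (0.791) and GC correction with the block (0.990). Mitochondrially encoded genes turned lower with GC correction (0.622), GC and length correction (0.459) and GC correction with the block (0.638). Interferon (0.661) and neural (0.977) lists turned with the 1 CPM filter. The log2 fold change of HSPB1 became 0.16 with GC correction, 0.13 with GC and length correction and 0.16 with GC correction and the block, and that of TNNT2 -0.0052 with limma-voom and -0.0053 with the block. The cause was not tested.

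With 1 library left out, with or without GC correction, adjusted p of lists ranged as follows. It ran from 0.196 to 0.977 for antioxidant genes, from 0.0266 to 0.163 for cholesterol, from 0.392 to 0.931 for oxidant-producing enzymes and from 0.0492 to 0.397 for ethanol metabolism. It ran from 0.00434 to 0.963 for endoderm, from 0.00326 to 0.0583 for p53, from 1.97e-06 to 0.0709 for cell cycle and from 0.0229 to 0.526 for chaperones. It ran from 9.03e-04 to 0.931 for mitochondrially encoded genes, from 0.00640 to 0.654 for cardiac transcription factors, from 0.0170 to 0.580 for epicardial markers and from 0.131 to 0.951 for the respiratory chain. It ran from 0.00432 to 0.989 for sarcomere, from 0.0189 to 0.646 for skeletal muscle and from 0.711 to 0.967 for interferon. The sarcomere list passed, as lower, without ethanol replicate 1, but with GC correction it did not. The mitochondrially encoded list turned lower and passed without ethanol replicate 3, both without GC correction (0.0334) and with it (9.03e-04). The skeletal muscle list passed, as higher, with GC correction and without control replicate 3 (0.0316) or ethanol replicate 3 (0.0189). Log2 fold changes ran from -0.20 to 0.044 for NPPA, from -0.33 to 0.064 for LRRN4, from -0.14 to 0.21 for HSPB1, from -0.032 to 0.13 for ADH5, from -0.027 to 0.23 for CYP2E1, from -0.028 to 0.38 for MYH6 and from -0.18 to 0.25 for TNNT2. MYH6 passed with GC correction and without ethanol replicate 3. The p53 list was lost without control replicate 3 and the cell cycle list without ethanol replicate 1, both without GC correction. The cause was not tested.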

Other observations

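The tests of GC content and of fibroblast-like cells were chosen after the results were seen, and the lists of further HIF, YAP and SRF targets were written after the main results but before their own values were looked at. P-values of these 3 lists were adjusted over the 3 alone, so they cannot be set beside those adjusted over the 34 fixed lists. Unadjusted, camera's p with an estimated correlation was 0.0258 for further HIF targets, 0.0312 for SRF targets and 0.00621 for the fixed hypoxia list. Of 23 targets of hypoxia-inducible factor (HIF) outside the fixed lists, 12 were higher and 0 lower. All 23 had positive log2 fold changes (median 0.31, camera adjusted p = 0.0468 with an estimated correlation). Among them were TMEM45A (0.57), the fucosyltransferase FUT11 (0.56), the oxidoreductase ERO1A (0.54), INSIG2 (0.52) and the glycogen branching enzyme GBE1 (0.50). Members named here were chosen after their values were seen.

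Of 19 tested targets of serum response factor (SRF), 9 were lower and 0 higher (median -0.28, adjusted p = 0.0468 with an estimated correlation). With GC correction 8 were lower and that call was lost (adjusted p = 0.114 with an estimated correlation). Lower targets included smooth muscle actin ACTG2 (-0.66), filamin FLNA (-0.60), PDLIM7 (-0.56) and the integrin ITGA5 (-0.48). Of 19 tested targets of the coactivator YAP, 7 were lower and 0 higher (median -0.27, adjusted p = 0.103 with an estimated correlation), including AMOTL2 (-0.47) and AMOTL1 (-0.42).

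The rise of hypoxia and glycolysis genes was set against the GC trend of the libraries. With that trend removed, 30 members of the 2 lists were higher, against 24 without the correction, while 497 of the 1649 calls ended, which argues against the trend as the whole cause. A candidate explanation is higher HIF activity, and the further HIF targets had a median log2 fold change of 0.35 with GC correction. What in the treated cultures would raise it was not tested.

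In the matrix list 18 members were lower with GC correction against 19 without it, which argues against the GC trend as the whole cause. With GC correction the 6 fibroblast markers outside the matrix list had log2 fold changes of -0.82 (TCF21), -0.55 (PDGFRB), -0.50 (DDR2), -0.35 (THY1), -0.058 (PDGFRA) and -0.016 (VIM), of which PDGFRB and DDR2 passed. They differed beyond their standard errors (chi-square test of Cochran's Q over edgeR standard errors, p = 5.25e-08). Without VIM, which many cell types express, the p of that test was 1.58e-05. With PDGFRB, TCF21, THY1 or DDR2 also left out, it ran from 4.69e-06 to 1.25e-04. Only with PDGFRA also left out was it 0.50. Besides VIM the difference thus rests on PDGFRA alone, so fewer fibroblast-like cells stay open as a cause. Lower YAP or SRF activity may contribute, as their further targets had medians of -0.14 and -0.13 with GC correction. Both medians were nearer 0 than without it, and neither list passed with an estimated correlation in that fit (adjusted p = 0.133 and 0.114). Bulk counts cannot tell lower activity of YAP or SRF from fewer cells that express their targets.

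The GC trend itself differed from library to library. Its range within the ethanol group was 0.690, more than the difference of 0.493 between the group means, which is consistent with a trend that belongs to single libraries. Ethanol replicate 1, at 0.173, lay above the lowest control at 0.141, but by less than the range of 0.290 within controls. A shift of every treated library by ethanol therefore stays open, and a shift in some of the libraries was not tested.

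The 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real division gave 1649 genes and 119 genes over 2-fold, each reached in 1 of the 10, and the highest of the others was 0 for both. It gave 9 lists, a number reached in 5 of the 10, and the highest of the others was 11. Each other division mixes control and ethanol libraries in both of its groups. A difference between control and ethanol would thus widen the spread within those groups and lower the gene count. The other divisions are therefore no measure of chance, for genes or for lists.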
